A study of Homo sapiens with 9 samples.

How the data were processed

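Gene expression was measured on Affymetrix HG-U133 Plus 2.0 arrays in HT29 cells, with 3 arrays each of untreated cells (Control), of cells incubated for 24 h with 1.68 µg/mL of caffeic acid (CA) and of cells incubated for 24 h with 7 µg/mL of instant caffeinated coffee (ICC). Groups and replicate numbers come from the labels, which do not say whether replicates were separate cultures or what the number marks. Total RNA was labelled with biotin, per the labels' protocols. The deposited intensity values were normalized with RMA, per the submitters' processing notes, and the series design text names GeneSpring GX for the analysis. The version of RMA and the summary settings are not given in the sources used here. The values were expected on a log2 scale before the data were examined, but the deposited table holds linear intensity, with medians per array between 43.8 and 46.6 and maxima between 23682 and 25995, so the log2 of each value was taken here. No value was missing.

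The table held 54675 probe sets, of which 62 were Affymetrix controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none or were not listed. Control probe sets and those with several or no genes were left out of the gene test. Of the single-gene probe sets, 41037 had an Entrez identifier in the RefSeq table, and 0 symbols were updated. Each of 19775 genes was represented by its brightest probe set over the 9 arrays, a choice that concerned 10523 genes with several. At least 2 arrays had exactly the same value in 54.0% of 54613 probe sets, and all 3 arrays of a group had the same value in 361 probe sets of Control, 463 of CA and 435 of ICC.

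Genes were tested with limma 3.58.1 in R 4.3.3, with a linear model of the 3 groups over the 9 arrays and moderated t-tests, for ICC against control, CA against control and ICC against CA. P-values were adjusted by the method of Benjamini and Hochberg over all genes, and an adjusted p under 0.05 passed. SE is that of the moderated test. With 3 arrays in each group an exact permutation test cannot give a p under 0.1, and sign flips of 3 pairs cannot give one under 0.25. The p-values measure only the spread between these arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

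Arrays with the same replicate number in different groups resembled each other. After each group's mean was taken from each gene, the correlation of the deviations lay between 0.327 and 0.518 in all 9 same-numbered pairs and between -0.436 and 0.0839 in the others, and for 9 of 9 arrays the closest array outside the group had the same number. The deviations of a group sum to 0, so positive values in same-numbered pairs bring negative ones in the others by construction. Because of the resemblance a model with the number as a block was fitted as well, and its values stand beside a result where it changes the call. The main test without the block was chosen before the data were examined.

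Changes in groups of genes were tested with limma's camera, with a preset correlation of 0.01 between genes, on 34 lists of at least 5 measured genes, written from general knowledge before the data were examined, with 731 of 812 list entries measured. Of 35 lists fixed, that of STAT5B, ATF2 and CCND1 was too small for this test. Camera with an estimated correlation, fry, and the adjustment of members over the list alone were computed as well. The last does not correct for the number of lists, and a gene can stand in several, so some members can pass with no effect. Genes were named by a rule fixed beforehand: the 10 highest and 10 lowest against control and 5 and 5 for ICC against CA among those that passed with all arrays of the groups apart, filled by the largest moderated t where too few passed. Names of uncharacterised loci were passed over, at most 4 members of a list were named by smallest p, and STAT5B, ATF2 and CCND1 were always given. HSD3B1, SSR3, TPPP3 and the probe set without a gene fall outside this rule and were named after they passed with the block, as were members that passed adjusted over the list alone with the block.

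The test was checked on simulated data for ICC against control, with 19775 genes and 200 changed genes. Noise was drawn independently for each gene, at its spread within the 3 groups. Of genes changed by 0.5 log2 (1.41-fold) 77% were recovered, of those changed by 1 log2 (2-fold) 98%, with 5 false calls and 0 calls where nothing was changed. With the block these were 91%, 100% and 9. A shift of the unfolded protein response list by -0.15 gave an adjusted p of 0.0138 and 0 other lists. The simulated genes were not correlated, so this check cannot show how often camera calls lists of correlated genes. The recovered shares hold for 200 changed genes and for normal noise at the moderated spread. With fewer changed genes the adjustment is stricter, so the shares do not show how often a few genes changed by as much would be called. The correlation that shared controls alone bring was taken from 100 simulations.

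Alternatives comprised quantile normalization applied again, centring on the median, leaving out dim genes or probe sets ending in _x_at or _s_at, the mean of a gene's probe sets, each probe set tested singly, a variance trend with robust moderation, array weights, the 2 compared groups only, other thresholds, and each array left out in turn. The block with quantile normalization, with single probe sets or with 1 array left out, and the omission of all arrays of 1 number, were added after the resemblance by number was seen. Scanner files were not used here.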

Results

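The effect of instant coffee and of caffeic acid, a phenolic acid found in coffee, on gene expression was measured in HT29, a human line established from a colon cancer. Cells were left untreated (Control), incubated with 7 µg/mL of instant caffeinated coffee (ICC) or incubated with 1.68 µg/mL of caffeic acid (CA), and treated cells were exposed for 24 h. Each group had 3 arrays, which made 9 in all. Intensity was recorded for 54675 probe sets and, after the choice of 1 probe set per gene, for 19775 genes. The median intensity of an array lay between 43.8 and 46.6, and the correlation between any pair of arrays across genes lay between 0.995 and 0.998. The number of arrays limits the precision of every value. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these arrays, which can be technical.

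Cells incubated with instant coffee were set against untreated cells to find which genes respond to the whole beverage. Among the genes that stood highest above control relative to their spread were ABCC12, a transporter of the ABC family, at +0.48 ± 0.068 log2 (SE, n = 3 arrays in each group, 1.40-fold), and the ubiquitin pseudogene UBBP1 at +0.56 ± 0.093. The erythropoietin receptor EPOR stood at +0.46 ± 0.10 and PPARGC1A, a coactivator of mitochondrial biogenesis, at +0.43 ± 0.092 (1.35-fold). ABCC12 was dim, with means of 4.07 log2 in ICC, 3.87 in CA and 3.58 in control, below the lower quartile of the arrays. PPARGC1A, at 4.67 in ICC and 4.24 in control, lay below their median. Lowest relative to their spread were OSTF1 at -0.45 ± 0.074 (1.36-fold), the selenoprotein SELENOT at -0.44 ± 0.074, glutamate dehydrogenase GLUD1 at -0.43 ± 0.081, the spliceosome protein SNRNP40 at -0.45 ± 0.089 and the sodium bicarbonate cotransporter SLC4A4 at -0.36 ± 0.073. MEPE, ZMYND15, KCNE4, SYTL3, PABPN1P1 and RPS6KA4 lay between +0.33 and +0.44. MTA2 and RBBP4, both subunits of the NuRD chromatin complex, lay with WDR76, MARCHF3 and MSL2 between -0.47 and -0.31. In each of these 20 genes the 3 treated arrays lay on 1 side of the 3 controls, which the choice by the largest moderated t favours. That 3 of 3 same-numbered pairs had the same direction follows from this. None of them passed the test over all genes, with an adjusted p of 0.539 for ABCC12 and of 0.614 for the other 19.

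Over all 19775 genes, limma called 0 genes at an adjusted p under 0.05 in ICC against control, with or without the replicate number as a block. At an unadjusted p under 0.05 there were 1529 genes, 1153 higher and 376 lower, where chance gives 989, and with the block there were 2453, of which 1664 were higher. After centring each array on its median, 806 genes were higher and 578 lower, so that the share of higher genes moved from 75.4% to 58.2%. All 3 ICC arrays lay above or below all 3 controls in 12.0% of the genes, where chance gives 10% for arrays that do not resemble each other by number. Probe sets tested singly gave 0 calls without the block and 2 with it. These were a probe set of SSR3, a subunit of the translocon-associated complex of the endoplasmic reticulum, at -0.72 log2 (1.65-fold, adjusted p 0.0415, without the block 0.430), and a probe set with no gene name here at -1.09 (2.12-fold, adjusted p 0.0116, without the block 0.441).

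Of the 34 gene lists tested in ICC against control, 0 passed limma's camera test at an adjusted p under 0.05, 2 had an unadjusted p under 0.05, and 0 passed with an estimated correlation or with fry. The lowest value was that of the unfolded protein response, the chaperones and folding enzymes of the endoplasmic reticulum. Its 19 genes had a median of -0.12 log2 with 13 below 0 (adjusted p 0.0842), and its members with the smallest p were DNAJB9 at -0.31 ± 0.13, EDEM1 at -0.19 ± 0.10 and HSP90B1 at -0.16 ± 0.089. Without the block the result depended on single arrays. The list passed without ICC replicate 3 (median -0.18, adjusted p 1.1e-04), Control replicate 2 (-0.17, 0.0141) or Control replicate 1 (-0.12, 0.0303) and with the mean of a gene's probe sets (-0.10, 0.00897). Its median was -0.038 without Control replicate 3, -0.051 without ICC replicate 1, -0.076 without ICC replicate 2 and -0.017 without probe sets ending in _x_at or _s_at. With the replicate block this list passed (adjusted p 0.0107), but not with an estimated correlation as well (adjusted p 0.941), nor with the block when Control replicate 1 (0.144) or ICC replicate 2 (0.124) was left out.

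The metallothioneins, small proteins that bind zinc and copper, listed with the zinc exporter SLC30A1, had a median of +0.15 with 7 of 8 above 0 (adjusted p 0.856). Single arrays moved it, to +0.029 without ICC replicate 1, +0.083 without Control replicate 3 and +0.23 without Control replicate 1. They passed fry with the block (adjusted p 0.0263), which tests the direction of the list alone, and not camera with the block (0.278). Adjusted over the list alone, 1 member passed in each of 3 lists, namely the sulfotransferase SULT1B1 at +0.43 ± 0.094 among the conjugation genes (adjusted p 0.0240) and PPARGC1A among the cAMP targets (0.0121) and the fatty acid oxidation genes (0.0177).

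With the replicate block these calls were kept and others were added, again adjusted over the list alone. Of the cAMP targets 5 passed, namely PPARGC1A (adjusted p 0.0153), PCK1 (0.0342), PDE3B, NR4A2 and PDE4B (0.0435 each), of which PPARGC1A and PDE4B, at +0.33, lay above control and the other 3 below it. In 4 further lists 1 member passed. These were the AhR target UGT1A6 at -0.26 (0.0494), the JAK-STAT target BCL6 at -0.39 (0.0163), the interferon response gene IFI6 at -0.45 (0.0225) and the Wnt target PROX1 at -0.28 (0.0404).

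Caffeic acid alone was set against untreated cells to find which genes respond to this single compound. The largest difference among the named genes was that of HINT3, a histidine triad hydrolase, at +1.38 ± 0.28 log2 (SE, n = 3 arrays in each group, 2.61-fold), whose 3 controls had an SD of 0.73. Lower than in untreated cells were the calcium-binding protein S100A2 at -0.62 ± 0.11 (1.53-fold), the cotransporter SLC4A4 at -0.63 ± 0.073 (1.54-fold) and HSD3B1, an enzyme of steroid hormone synthesis, at -0.65 ± 0.35 (1.57-fold), each in 3 of 3 same-numbered pairs. The other named genes above control were FST, EPOR, ABCC12, GP6, SULT1B1, DGKK, ADCY5, SPIN4 and DHX29, between +0.27 and +0.46. Below control lay CYP2A13, PDZRN3, CDA, H2BC13, SLC38A5, MARCHF3, IGFBP6 and TMPRSS4, between -0.46 and -0.31. Without the block none of these genes passed, with adjusted p of 0.0993 for SLC4A4 and 0.996 for the others. With the replicate block S100A2, SLC4A4 and HSD3B1 passed (adjusted p 0.0472 each), where their SE was 0.068, 0.072 and 0.078. All 3 calls were lost with the block after quantile normalization was applied again. With the block and any 1 array left out none of these 3 passed (adjusted p 0.0908 to 0.311), while with the block and without Control replicate 3 HINT3 passed, at +1.03 (adjusted p 0.0189).

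**Figure D1:**
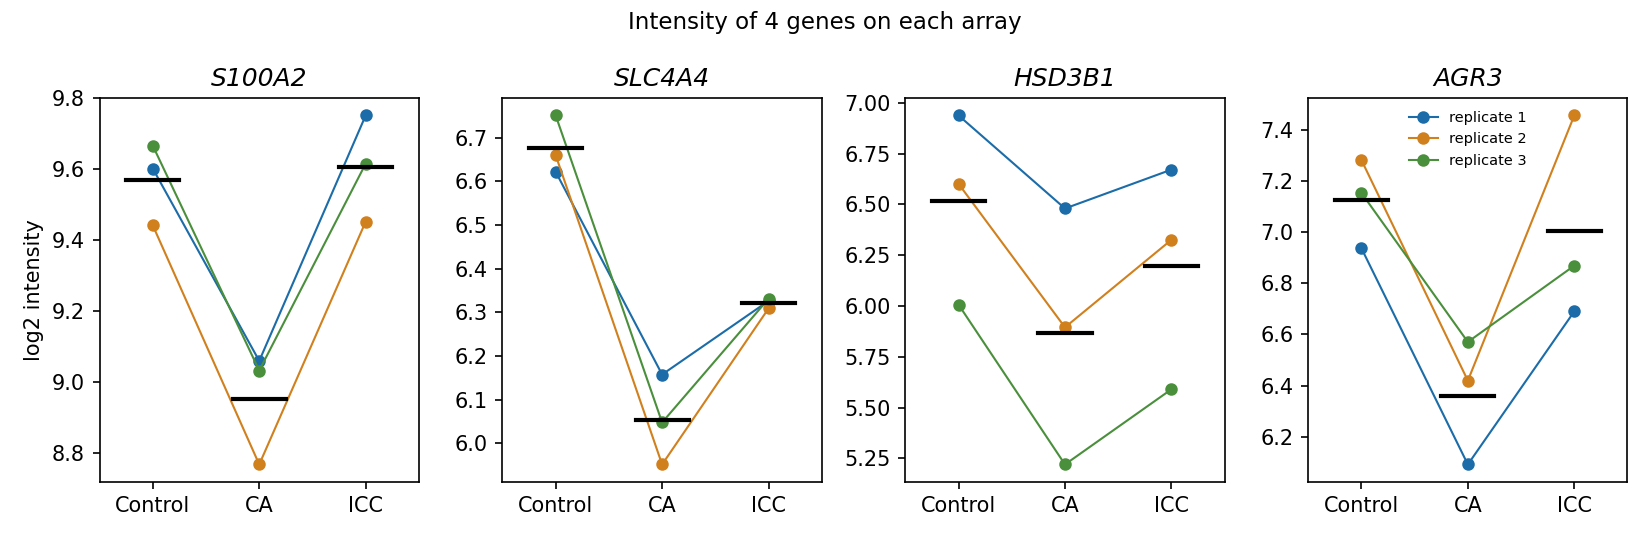
Intensity on the log2 scale of S100A2, SLC4A4, HSD3B1 and AGR3 on each of the 9 arrays by group, with points for arrays, lines joining arrays of the same replicate number and a black bar for the group mean. In each gene the 3 CA arrays lie below the control of the same number, with mean differences of -0.62, -0.63, -0.65 and -0.76.

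Over all 19775 genes, limma called 0 genes in CA against control without the block and 3 with it, all lower. The block called 0 after quantile normalization was applied again, and 0 when probe sets were tested singly. At an unadjusted p under 0.05 there were 883 genes, 505 higher and 378 lower, where chance gives 989, and with the block there were 1688, of which 798 were higher and 890 lower. After quantile normalization was applied again these were 674 higher and 336 lower, and with the block as well 1057 and 783, which turns the balance found with the block. Without dim genes 155 were higher and 186 lower. All 3 CA arrays lay above or below all 3 controls in 7.86% of the genes, where chance gives 10% for arrays that do not resemble each other by number.

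At the level of gene lists, 2 of 34 passed in CA against control. The unfolded protein response list fell, with a median of -0.13 log2 and 15 of 19 genes below 0 (camera, adjusted p 0.0379, and adjusted p 0.980 with an estimated correlation). Its members with the smallest p were DNAJB9 at -0.37 ± 0.13, HSP90B1 at -0.19 ± 0.089, SDF2L1 at -0.29 ± 0.14 and DNAJB11 at -0.19 ± 0.11, all chaperones or their cofactors, of which 0 passed over all genes or, without the block, adjusted over the list alone. With the block DNAJB9 (adjusted p 0.0264) and SDF2L1 (0.0330) passed adjusted over the list alone. The Wnt targets fell, with a median of -0.087 and 16 of 20 below 0 (adjusted p 0.0496, and adjusted p 0.980 with an estimated correlation), among them TNFRSF19 at -0.20 ± 0.086, the protease MMP7 at -0.33 ± 0.21, ZNRF3 at -0.12 ± 0.081 and PROX1 at -0.30 ± 0.21. Of these MMP7 (0.0230) and PROX1 (0.0224) passed adjusted over the list alone with the block. Fry passed 0 lists, and with the block it passed 2, the Wnt targets (adjusted p 0.0117) and the metallothioneins.

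Both list calls in CA depended on single arrays when the block was not used. The unfolded protein response call was lost without Control replicate 3 (median -0.026, adjusted p 0.152) or CA replicate 1 (-0.062, 0.386). The Wnt call was lost without Control replicate 1 (-0.067, 0.115), Control replicate 3 (-0.068, 0.160), CA replicate 2 (-0.035, 0.249) or ICC replicate 3 (-0.087, 0.0514). Without probe sets ending in _x_at or _s_at both missed the threshold, the unfolded protein response at a median of -0.092 (adjusted p 0.196) and the Wnt targets at a median of -0.12 (0.1502), which is farther from 0 than before. The Wnt call was also lost without dim genes (-0.084, 0.109) or with array weights (-0.092, 0.0511). With the block the adjusted p of both lists was 0.00153. The Wnt call then held without any 1 array (0.00157 to 0.0181) and the unfolded protein response call was lost only without Control replicate 1 (0.0837), while with the block and an estimated correlation neither passed (adjusted p 0.428 and 0.498).

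The goblet cell markers, genes of mucus-secreting cells, had a median of -0.12 log2 with 11 of 18 below 0 (adjusted p 0.0527, with the replicate block 0.00218, and adjusted p 0.428 with the block and an estimated correlation). Without the block the list passed without Control replicate 1 (median -0.13, adjusted p 6.5e-04), CA replicate 2 (-0.15, 0.00382), CA replicate 3 (-0.13, 0.0155) or ICC replicate 2 (-0.12, 0.0366). It also passed without dim genes (-0.16, 0.00604), with array weights (-0.13, 0.00950), with arrays centred on their medians (-0.12, 0.0491) and with only CA and control arrays (-0.12, 0.0413). The median was -0.050 without CA replicate 1 (adjusted p 0.407), -0.079 without Control replicate 2 (0.286) and -0.069 with the mean of a gene's probe sets (0.121). With the block it passed without any 1 array (0.00106 to 0.0279). AGR3, a disulfide isomerase of secretory cells, was the 1 member that passed adjusted over the list alone, at -0.76 ± 0.19 (1.70-fold, adjusted p 0.0382, over all genes 0.996), followed by MUC13 at -0.21 ± 0.072, TFF2 at -0.16 ± 0.080 and REG4 at -0.29 ± 0.15. With the block 5 passed so, namely AGR3 (adjusted p 0.00112), AGR2 (0.00472), REG4 (0.0114), MUC13 (0.0434) and MUC5AC (0.0443).

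The metallothionein list had a median of +0.13 with 7 of 8 above 0 (adjusted p 0.202). Without the block it passed without Control replicate 1 (median +0.24, adjusted p 0.00294) or CA replicate 3 (+0.18, 0.0286) and with array weights (+0.18, 0.0460). Its median was +0.055 without Control replicate 3 and +0.052 without CA replicate 1. With the block it passed camera and fry (adjusted p 0.0117 in each), and it did not with the block and an estimated correlation (adjusted p 0.428) or, with the block, without Control replicate 2 (0.0909). MT1X stood at +0.20 ± 0.12, MT1F at +0.18 ± 0.12 and MT2A at +0.18 ± 0.16. Enterocyte markers, genes of absorptive cells, had a median of -0.0070 (adjusted p 0.177), with CEACAM1 at -0.41 ± 0.11, the carbonic anhydrase CA2 at -0.33 ± 0.13 and CEACAM6 at -0.44 ± 0.18, all 3 of which passed adjusted over the list alone only with the block (adjusted p 0.00541, 0.0433 and 0.00541). The same held for PCK1 among the cAMP targets (0.0280), the heat shock protein CRYAB at +0.34 (0.0172), and CD14 at -0.39 and LAPTM5 at -0.37 among the leukocyte markers (0.0255 each).

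**Figure D2:**
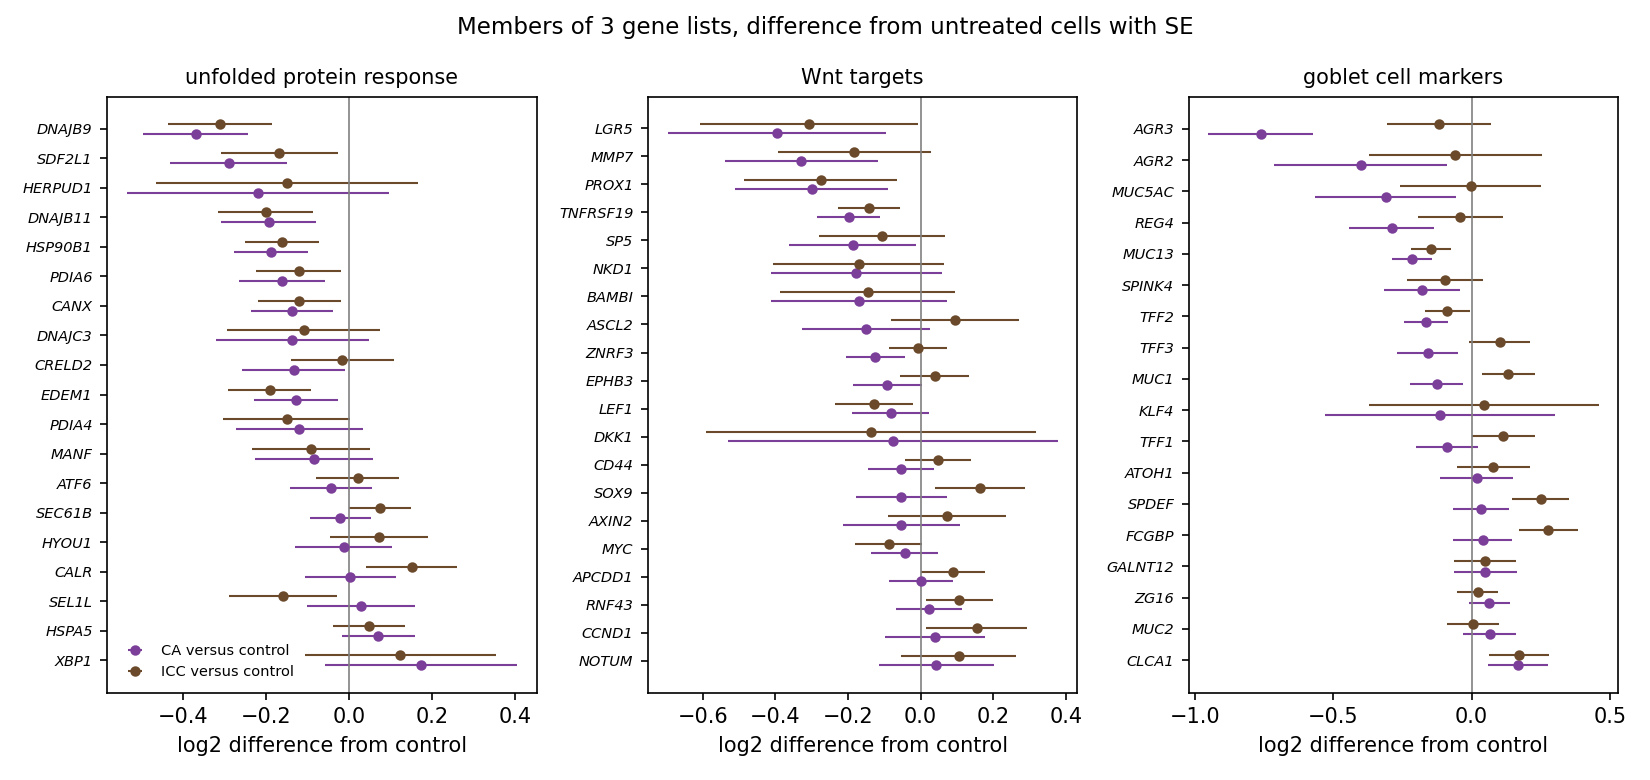
Difference from untreated cells on the log2 scale (x axis) with its SE for each measured member (y axis) of the unfolded protein response, Wnt target and goblet cell lists, in purple for CA and in brown for ICC. In CA 15 of 19, 16 of 20 and 11 of 18 members lie below 0, and in ICC 13, 11 and 7 do.

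ICC and CA were then set against each other, at doses that differ (7 and 1.68 µg/mL), as the test of the difference between the treatments. S100A2 was +0.65 ± 0.11 log2 higher in ICC than in CA (SE, n = 3 arrays in each group, 1.57-fold, 3 of 3 pairs), with an adjusted p of 1.00. With the replicate block its SE was 0.068 and its adjusted p 0.0388. The water channel AQP5 stood at +0.52 ± 0.088, VGLL1 at +0.28 ± 0.061, the protease TMPRSS4 at +0.36 ± 0.080 and PHYHD1 at +0.37 ± 0.083. Lower in ICC were the transcription factor TFAP2A at -0.39 ± 0.071, OSTF1 at -0.30 ± 0.074, the gap junction protein GJA1 at -0.28 ± 0.078, CEP44 at -0.26 ± 0.072 and ZFYVE16 at -0.25 ± 0.072. GJA1 was dim, with means of 3.29 log2 in ICC and 3.58 in CA, below the lower quartile of the arrays. CEP44 turned to +0.071 without probe sets ending in _x_at or _s_at. The adjusted p of each was 1.00. With the block and any 1 array left out S100A2 did not pass (adjusted p 0.0624 to 0.495).

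Over all 19775 genes, limma called 0 genes between ICC and CA without the block and 1, S100A2, with it. Probe sets tested singly with the block gave 0 calls. At an unadjusted p under 0.05 there were 532 genes, 434 higher and 98 lower in ICC, where chance gives 989, and with the block 1178, of which 916 were higher. After quantile normalization was applied again, 357 were higher and 173 lower, and after centring on the medians 233 were higher and 220 lower. The share of higher genes moved from 81.6% to 67.4% and 51.4%. The 3 arrays of the groups did not overlap in 5.87% of the genes, where chance gives 10% for arrays that do not resemble each other by number. Of the 34 lists 1 passed. The goblet cell markers lay higher in ICC than in CA, with a median of +0.18 and 15 of 18 above 0 (adjusted p 0.0192, adjusted p 0.986 with an estimated correlation, fry 0.728). AGR3 stood at +0.64 ± 0.19, the mucin MUC1 at +0.26 ± 0.10, the trefoil factor TFF3 at +0.26 ± 0.11 and FCGBP at +0.24 ± 0.11, of which 0 passed over all genes or, without the block, adjusted over the list alone.

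With the replicate block the goblet cell call had an adjusted p of 1.8e-04 (adjusted p 0.797 with the block and an estimated correlation) and held without any 1 array (1.0e-04 to 0.00860). Adjusted over the list alone, 6 members then passed, namely AGR3 (adjusted p 0.00441), AGR2 (0.0148), MUC1 and REG4 (0.0262 each), MUC5AC (0.0471) and TFF3 (0.0472). The sulfotransferase SULT2B1 at +0.31 (0.0424) and the leukocyte marker LAPTM5 at +0.42 (0.0132) passed so too. Without the block the goblet cell call was lost without CA replicate 1 (median +0.091, adjusted p 0.341) or ICC replicate 2 (+0.11, 0.270), and with the mean of a gene's probe sets (+0.11, 0.0888). Without probe sets ending in _x_at or _s_at it missed the threshold at a median of +0.20 (adjusted p 0.0680).

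The differences of ICC and CA from the shared controls had a correlation of 0.656 across genes, which are not independent replicates, where 100 simulations of unchanged groups on the same 3 controls gave 0.501 (0.476 to 0.521). Their covariance was 0.00874 against a simulated 0.00610, or 0.00370 where the simulated noise was that left after the replicate number, which moves the excess from 0.00263 to 0.00503. Of the genes 72.4% had the same sign against a simulated 66.7%. At an unadjusted p under 0.05, 276 genes were higher in both and 83 were lower in both, 359 in all, where the simulation gave 218.5 (182 to 263) and independent lists of these sizes would share 29.4 and 7.19. The observed correlation had an SD of 0.0786 over the fits with 1 array left out. Leaving out an array also changes the correlation that shared controls alone bring, so this SD cannot be set against the simulated range. As genes are not independent replicates, the simulated ranges do not decide whether the excess over shared controls is a response. ABCC12, EPOR, SULT1B1 and HINT3 lay above control and SLC4A4 and MARCHF3 below it in both treatments. HINT3, named here for ICC after its values were seen, stood at +1.27 ± 0.28 in ICC (2.41-fold, adjusted p 0.614). At an adjusted p under 0.05, limma called 0 genes in both. The 3 controls could not be divided between the treatments.

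The transcription factors STAT5B and ATF2 and cyclin D1, encoded by CCND1, were chosen before the data were examined, as genes known from published work on coffee polyphenols. Whether that work used these samples is not given in the sources used here, so the genes are not independent evidence. At its brightest probe set STAT5B differed from control by -0.025 ± 0.080 (95% interval -0.20 to +0.15) in ICC and +0.040 ± 0.080 (95% interval -0.14 to +0.22) in CA. All 3 control arrays held exactly the same STAT5B value there, 7.23 log2, so the SD of the controls was 0. ATF2 differed by +0.18 ± 0.10 (95% interval -0.035 to +0.40) in ICC and +0.067 ± 0.10 (95% interval -0.15 to +0.28) in CA, and CCND1 by +0.15 ± 0.14 (95% interval -0.15 to +0.46) and +0.039 ± 0.14 (95% interval -0.27 to +0.35). Adjusted over the list alone the p-values were 0.757, 0.274 and 0.435 in ICC and 0.782 for each in CA, so 0 of 3 passed. In ICC minus CA the differences were -0.065 ± 0.080 (95% interval -0.24 to +0.11), +0.11 ± 0.10 (95% interval -0.10 to +0.33) and +0.12 ± 0.14 (95% interval -0.19 to +0.42), with 0.432 for each. Other probe sets of the same genes went other ways. An ATF2 probe set with the suffix _s_at lay at -0.57 ± 0.10 in ICC and -0.44 ± 0.10 in CA (adjusted p over all probe sets 0.259 and 0.986, with the block 0.106 and 0.398). A STAT5B probe set with the suffix _x_at lay at +0.39 ± 0.091 and +0.42 ± 0.091 (adjusted p 0.441 and 0.986), and the other 3 of STAT5B lay between +0.050 and +0.26 in ICC. The 2 probe sets of CCND1 lay at +0.15 ± 0.14 and +0.12 ± 0.18 in ICC.

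**Figure D3:**
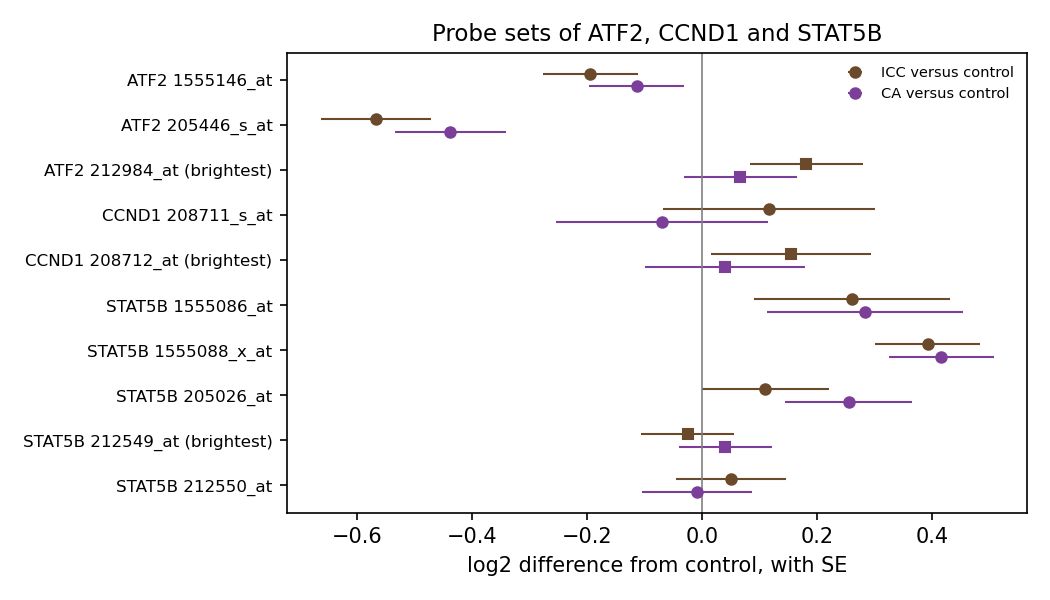
Difference from untreated cells on the log2 scale (x axis) with its SE for every probe set of ATF2, CCND1 and STAT5B (y axis), in brown for ICC and in purple for CA, with squares for the brightest probe set of each gene. ATF2 lies at +0.18 at its brightest probe set and at -0.57 at the one with the suffix _s_at in ICC.

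The other lists did not pass the main test with all arrays in either treatment. Under some alternatives further lists passed. Their values are given as the median log2 difference from control in ICC and in CA, with the adjusted p of the main test. Detoxification genes were among them, since coffee compounds are known to act on xenobiotic sensors. Targets of NRF2, the antioxidant regulator, stood at +0.0053 and -0.017 (adjusted p 0.856 and 0.261), and targets of the aryl hydrocarbon receptor AhR at +0.032 and +0.11 (adjusted p 0.856 and 0.605). Phase II conjugation and transport genes stood at -0.024 and -0.059 (adjusted p 0.856 and 0.189). CYP1A1, a classical AhR target, stood at +0.11 ± 0.11 and +0.25 ± 0.11, the glucuronosyltransferase UGT1A6 at -0.26 ± 0.081 and -0.21 ± 0.081, and SULT1B1 in CA at +0.38 ± 0.094. Genes of folate metabolism stood at +0.029 and -0.0075 (adjusted p 0.910 and 0.769).

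None of the other signalling and stress lists passed the main test with all arrays in either treatment. The JAK-STAT targets stood at +0.022 and -0.037 (adjusted p 0.889 and 0.769), and the AP-1 and immediate early genes at +0.0070 and -0.070 (adjusted p 0.856 and 0.268). The cAMP and CREB targets stood at +0.031 and -0.072 (adjusted p 0.897 and 0.605), and the purine receptors and phosphodiesterases, on which caffeine acts, at +0.0096 and -0.014 (adjusted p 0.886 and 0.769). Inflammatory targets of NF-kB stood at +0.042 and -0.046 (adjusted p 0.856 and 0.268) and the interferon response genes at +0.0037 and +0.072 (adjusted p 0.856 and 0.900). The ATF4 and amino acid response genes stood at +0.083 and +0.033 (adjusted p 0.889 and 0.900) and heat shock proteins at +0.0042 and -0.030 (adjusted p 0.901 and 0.769). PCK1, a cAMP target and enzyme of gluconeogenesis, stood at -0.30 ± 0.10 and -0.35 ± 0.10.

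Some of these lists passed in opposite directions when 1 array was left out. In CA without the block the ATF4 list was directed down without CA replicate 2 (adjusted p 1.0e-05) or Control replicate 3 (0.00687) and up without CA replicate 3 (0.00249) or Control replicate 1 (0.0296). The interferon list in CA was directed up without Control replicate 1 (5.4e-04) or CA replicate 3 (0.00249) and down without CA replicate 1 (0.0384). In ICC the ATF4 list was directed down without Control replicate 3 (0.0422), and with the block it was directed up without Control replicate 1 (4.4e-10) or ICC replicate 1 (0.00592). In ICC against CA the ATF4 and AP-1 lists were directed up without CA replicate 2 (2.6e-08 and 1.2e-05) and down without CA replicate 3 (0.0120 and 0.0422).

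Cell cycle and survival lists also did not pass the main test with all arrays. The G1/S genes stood at +0.053 and -0.010 (adjusted p 0.862 and 0.936), and the G2/M genes at +0.040 and +0.029 (adjusted p 0.889 and 0.261). CDK inhibitors and p53 targets stood at +0.021 and -0.0043 (adjusted p 0.889 and 0.845), the apoptosis regulators at -0.033 and -0.042 (adjusted p 0.856 and 0.605) and DNA repair genes at +0.0053 and -0.013 (adjusted p 0.856 and 0.936). CDKN1B, the CDK inhibitor p27, stood at +0.27 ± 0.070 and +0.19 ± 0.070, and cyclin E2, CCNE2, at +0.17 ± 0.092 and +0.30 ± 0.092. The enzymes of DNA methylation and histone deacetylation stood at +0.063 and +0.017 (adjusted p 0.856 and 0.818), with HDAC8 at -0.28 ± 0.090 and -0.30 ± 0.090. Ribosomal proteins stood at +0.024 and +0.0076 (adjusted p 0.856 and 0.605).

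Among metabolic lists, cholesterol synthesis stood at -0.027 and -0.072 (adjusted p 0.856 and 0.177), and fatty acid synthesis and lipid storage at +0.016 and -0.038 (adjusted p 0.889 and 0.189). Fatty acid oxidation and PPAR targets stood at +0.022 and +0.0041 (adjusted p 0.991 and 0.819), glycolysis and hypoxia at +0.046 and -0.021 (adjusted p 0.862 and 0.261) and oxidative phosphorylation at +0.015 and +0.0077 (adjusted p 0.889 and 0.900). The lipid droplet protein PLIN2 stood at -0.18 ± 0.12 and -0.28 ± 0.12. Among lists of cell identity, goblet cell markers in ICC stood at +0.033 (adjusted p 0.910), Wnt targets in ICC at -0.048 (0.856), and enterocyte markers in ICC at +0.028 (0.910). Intestinal stem cell markers stood at +0.047 and -0.063 (adjusted p 0.856 and 0.232) and genes of epithelial-mesenchymal transition at +0.016 and -0.043 (adjusted p 0.889 and 0.309). Markers of cells that the line should not hold did not pass either. Fibroblast markers stood at +0.12 and +0.026 (adjusted p 0.344 and 0.261), leukocyte markers at +0.054 and +0.022 (adjusted p 0.862 and 0.900) and endothelial markers at +0.062 and -0.0012 (adjusted p 0.856 and 0.845).

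In ICC against CA the lists other than the goblet cell markers had adjusted p from 0.162 to 0.971, the lowest being those of the AhR targets at a median of -0.061 and the enterocyte markers at +0.059. Fry with the block passed the Wnt targets, at a median of +0.086 (adjusted p 0.0484), and not the goblet cell markers (0.189). In several lists the median and the test had opposite signs. Camera sets a list against the other genes, and the median of all genes lay at +0.028 in ICC against control and +0.024 in ICC against CA, but some of these lists had a median above that of all genes. In ICC against control the lists with opposite signs were the NRF2, AhR, JAK-STAT, AP-1, cAMP, purine receptor, CDK inhibitor, NF-kB, interferon, heat shock, fatty acid synthesis, glycolysis, oxidative phosphorylation, enterocyte, stem cell, mesenchymal transition and DNA repair lists, all with a median above 0 and a test directed down. In CA they were the interferon, fatty acid oxidation, oxidative phosphorylation and leukocyte lists (median above 0, directed down) and the folate list (median below 0, directed up), while the G1/S and DNA repair lists had a mean above 0 and a test directed down. In ICC against CA they were the JAK-STAT, G2/M, CDK inhibitor, unfolded protein response, oxidative phosphorylation, ribosomal and folate lists (median above 0, directed down), and the apoptosis list had a mean above 0. Median and mean parted in ICC for the NRF2, AhR, interferon, glycolysis, stem cell and DNA repair lists, whose means lay below 0, and in CA for the interferon response genes they stood at +0.072 and +0.019.

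The 3' minus 5' signal of GAPDH was -0.010 ± 0.028 log2 in Control, +0.0089 ± 0.024 in CA and +0.042 ± 0.045 in ICC (SD, n = 3), and that of ACTB was +0.26 ± 0.083, +0.32 ± 0.031 and +0.33 ± 0.083. Two-sided exact permutation tests between groups gave p from 0.2 to 0.9 for these measures and from 0.6 to 1 for the hybridisation spikes, where 3 arrays against 3 cannot go below 0.1. Within replicate numbers, ICC lay above control in 3 of 3 pairs for GAPDH (+0.061, +0.020 and +0.075) and for ACTB (+0.073, +0.11 and +0.031), and CA in 3 of 3 for GAPDH (+0.020, +0.030 and +0.0072) and 2 of 3 for ACTB. An exact test by sign flips gave p = 0.25 for each of the 3 sets of pairs on 1 side, the smallest that 3 pairs allow.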

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

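The tests of the noise and of the low level of probe sets other than the brightest were chosen only after the result was seen, and so was that of dim probe sets for the resemblance by number.

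A difference between the treatments marked 2 results. The goblet cell markers had a median of +0.18 log2 in ICC minus CA, with a test of the difference itself (camera, adjusted p 0.0192, and adjusted p 0.986 with an estimated correlation), and S100A2 lay +0.65 higher in ICC than in CA (block, adjusted p 0.0388, without the block 1). A signal outside the tested genes marked the third, a probe set with no gene name here that lay at -1.09 in ICC against control (block, adjusted p 0.0116, without the block 0.441).

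Whether any grouping of the arrays gives as much was tested by regrouping the 6 arrays of each comparison in 10 ways, which are too few for a share under 0.05. By genes with an unadjusted p under 0.05, the real grouping gave 1529 in ICC against control, with 1140 the highest other (1 of 10 as large), 883 in CA against control against 1694 (6 of 10), and 532 in ICC against CA against 1527 (9 of 10). By gene lists it gave 2 against 13 in CA against control (10 of 10) and 1 against 15 in ICC against CA (9 of 10). In ICC against control it gave 0 lists against 13, and a count of 0 makes all 10 as large by construction, so this tests nothing. In CA against control and ICC against CA, some other groupings called several times the real count of lists. All these list counts rest on camera with its preset correlation between genes. With an estimated correlation the real grouping called 0 lists in both comparisons, and the other groupings were not counted in that way. The counts therefore cannot tell a structure of the samples from calls that the preset correlation allows. Among the 4 groupings that part every same-numbered pair, with the block, the real grouping gave 2453, 1688 and 1178 genes against highest others of 940, 1082 and 1340, and 1, 4 and 1 lists against 7, 11 and 6, so the replicate number does not account for all of the list calls in other groupings.

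More genes lay higher than lower in ICC against control, 75.4% of those with an unadjusted p under 0.05. An offset of dim probe sets could contribute, as 62.2% were higher among genes above the median level and 86.3% below it, which lies between the bounds set and leaves this open. A single ICC array could contribute too, as 63.3% were higher without ICC replicate 1, also between the bounds. Other groupings of the 6 arrays put up to 80.1% on the larger side. A response to coffee as the biological explanation stays undecided.

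Probe sets that are not the brightest of their gene lay lower in ICC in 260 of 337 cases at an unadjusted p under 0.05 and 1.3-fold, and of the brightest 15 of 52 did, while the brightest probe set had the same sign in 227 of the 337 (67.4%). Of those without the suffixes _s_at and _x_at 79.1% were lower, and of those above the median gene level 79.5% (210 probe sets, binomial SE 2.78). The pattern was therefore not confined to probe sets shared between transcripts or to those of low level. A binomial SE treats probe sets on the same arrays as independent, and other groupings reach such shares. Neither explanation is thus excluded as a contribution. Other noise of these probe sets stays open, as the share of 77.2% is the pattern itself and other groupings of the 6 arrays put up to 83.7% on 1 side (up to 76.7% of at most 53 such probe sets in those that part every same-numbered pair). A single array could contribute, as 65.6% were lower without Control replicate 2 (binomial SE 2.15, 488 probe sets), and the share was 61.2% without ICC replicate 2 and 87.9% without ICC replicate 1. The 3' minus 5' signal of GAPDH and ACTB lay above control in ICC in 3 of 3 same-numbered pairs, and whether this contributes was not tested. A response to coffee as the biological explanation stays undecided.

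Arrays with the same replicate number resembled each other across groups. If an intensity-dependent trend were the cause, its removal would have ended this. After the removal the lowest correlation of deviations over the 9 pairs was 0.344, which argues against this explanation. Among genes above the median level the lowest was 0.454, so the resemblance was not confined to dim probe sets. Noise that is independent between arrays can only weaken such a correlation, so this value does not test it. No biological explanation was tested.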

How the results depend on the processing

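The block with quantile normalization, with single probe sets or with 1 array left out, and the omission of all arrays of 1 number, were chosen only after the resemblance by number was seen. Named genes kept their direction in 1851 of 1885 values under alternatives, and 34 changed it. Most of these genes were chosen by the largest moderated t and refitted on the same arrays, so a kept direction is no independent support. The cause was not tested for any change below unless stated. The block changed no other call of the tests given in the report.

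Genes changed numbered 90, 53 and 25 (ICC against control, CA against control, ICC against CA) at an unadjusted p under 0.05 and 1.3-fold, by construction a looser rule, 1 in CA at an adjusted p under 0.1, 3 in CA and 1 in ICC against CA with the block, 2 in ICC against CA with the block and quantile normalization, where TPPP3 joined S100A2, and 2 in ICC against control with single probe sets and the block. With the block and quantile normalization 0 genes changed in CA. With single probe sets and the block 0 changed in CA and 0 in ICC against CA. Gene lists past the threshold numbered 0 in CA and 0 in ICC against CA with an estimated correlation and with fry, 4 in CA without dim genes, 1, 4 and 0 with the mean of probe sets, 0 in CA and 0 in ICC against CA without _x_at and _s_at probe sets, 4 in CA and 3 in ICC against CA with array weights, 1 in ICC and 4 in CA with the block, and 1 in ICC and 5 in CA with the block and quantile normalization.

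With the mean of a gene's probe sets STAT5B in ICC stood at +0.16, ATF2 at -0.19 in ICC, -0.16 in CA and -0.032 in ICC minus CA, and CCND1 in CA at -0.015, since probe sets of these genes differ. CEP44 in ICC minus CA stood at +0.071 without _x_at and _s_at probe sets. Single probe sets of ATF2 stood at -0.19 and -0.57 in ICC, -0.11 and -0.44 in CA and -0.080 and -0.13 in ICC minus CA, those of STAT5B at +0.26, +0.39, +0.11 and +0.050 in ICC, -0.0090 in CA and +0.059 in ICC minus CA, and 1 of CCND1 at -0.070 in CA.

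Without all arrays of number 1 the unfolded protein response call in CA was lost (median -0.086, adjusted p 0.296), as was the goblet cell call in ICC against CA (+0.12, 0.206), and the unfolded protein response list in ICC had -0.017, 0.407. Without number 3 the Wnt call in CA was lost (-0.091, 0.163). Fewer arrays were fitted in each case. With arrays left out the ATF4 list passed in either direction in all 3 comparisons, the interferon list in CA and the AP-1 list in ICC against CA.

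With arrays left out, with or without the block, gene lists past the threshold ranged from 0 to 3 in ICC, 1 to 11 in CA and 0 to 8 in ICC against CA, and genes changed in CA from 0 to 1. The correlation between treatments ranged from 0.541 to 0.765. STAT5B ranged from -0.063 to +0.024 in ICC, -0.029 to +0.12 in CA and -0.14 to +0.013 in ICC minus CA, CCND1 in CA from -0.044 to +0.12, and ATF2 from -0.032 to +0.12 in CA and -0.025 to +0.19 in ICC minus CA. Where a group was left with 2 arrays the pooled spread of all groups was used. Dim genes limit precision, as the lower quartile of intensity lay between 17.5 and 18.2 where the minimum lay between 6.49 and 7.00.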

Other observations

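The comparison of replicate numbers across the groups was chosen only after the result was seen. Arrays with number 1 had higher interferon genes than those with numbers 2 and 3, whatever the treatment (3 arrays for each number). PSMB9, a subunit of the immunoproteasome, rose by +1.56 ± 0.075 log2 (SE, n = 3) against number 2. In the interferon response list 30 of 30 genes lay higher in number 1 than in number 2, with a median of +0.61 (camera, adjusted p 1.8e-22, and adjusted p 0.359 with an estimated correlation), and 30 of 30 higher than in number 3, with a median of +0.76 (adjusted p 6.1e-34, and adjusted p 0.238 with an estimated correlation). Against number 2 the G2/M genes had a median of +0.23 (adjusted p 1.7e-09) and the inflammatory NF-kB genes a median of +0.36 (adjusted p 9.4e-07), each with an adjusted p of 0.359 with an estimated correlation. The mean of the interferon list on each array was 10.46, 9.72 and 9.67 in Control, 10.39, 10.01 and 9.50 in CA and 10.33, 9.81 and 9.66 in ICC, by number.

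Number 2 had higher immediate early and amino acid response genes than number 3. EGR1 rose by +2.05 ± 0.12 log2, FOS by +1.89 ± 0.17, DDIT4 by +2.05 ± 0.37 and CHAC1 by +1.87 ± 0.33 (SE, n = 3). The AP-1 list had a median of +0.66 with 23 of 23 above 0 (adjusted p 4.1e-19, and adjusted p 0.181 with an estimated correlation), and the ATF4 list +0.64 with 23 of 24 above 0 (adjusted p 7.3e-20, and adjusted p 0.244 with an estimated correlation). The lists called between treatments also differed by number. For 1 minus 2, 1 minus 3 and 2 minus 3 the unfolded protein response had medians of +0.0031, -0.16 and -0.17 (camera, adjusted p 0.467, 2.5e-05 and 4.2e-04). The Wnt targets had +0.21, +0.051 and -0.15 (2.2e-04, 0.556 and 4.2e-04). The goblet cell markers had -0.11, -0.072 and +0.019 (1.9e-04, 0.0104 and 0.561). With an estimated correlation none of these passed (adjusted p 0.181 to 0.835). With limma, 760 genes passed between numbers 1 and 2, 901 between 1 and 3 and 343 between 2 and 3. In F-tests of the model with number and treatment, 1217 genes passed for any number and 0 for any treatment (at an unadjusted p under 0.05, 4331 and 1955). Pairwise tests of treatments with the block called 3 genes in CA against control and 1 in ICC against CA.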
